A study of Mus musculus with 2 samples.

How the data were processed

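H3K4me1 ChIP-seq was analysed from the deposited peak lists of 2 biological replicates of mouse neural tube at embryonic day 11.5. Each replicate was a pool of embryos of both sexes, with 2 technical replicates and fragments of 300 to 500 bp, per the labels. There were 4 lists on mm10: 1 for each replicate, 1 called on both replicates together and 1 of replicated peaks, per the file headers and labels. The aligner, the peak caller, its thresholds and the control library's treatment were not given in the sources used here. The deposited lists hold for each peak a fold enrichment, which is a linear ratio over the authors' background, and the −log10 of a p-value and of a q-value, as the authors' caller wrote them. These values were used to describe, rank or filter peaks within a list, and, in 1 test of the closing section, the lowest values of the joint list were applied to the replicates. The smallest −log10 p was 2.01 in replicate 1 and 2.03 in replicate 2, and 17.2% and 18.2% of the replicates' peaks had a q above 0.05, so the lists are permissive. No counts of reads were in the lists; depth was unknown, and a list's length can follow depth as well as the tissue. All columns of the series lists could be placed.

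Positions were compared with the GRCm38 sequence and the GENCODE vM21 genes, the same build, and all peaks lay within the chromosome ends. Chromosomes 1 to 19 and X were used, and the lists had no peaks on Y. A gene's TSS is the start of its annotated span, over 21728 protein coding genes. A peak was shared when its overlap with a peak of the other list reached 50% of either peak, and 100 circular shifts per chromosome gave the overlap of random positions. Genome classes were taken from peak midpoints, and the TSS profile from steps of 100 bp. For gene lists, the kb covered by peaks within 50 kb either side of the TSS were taken in each replicate, the list's median computed, and the mean and SD of the replicates' medians reported. Random lists (10000, and 1000 for the receptor genes) were drawn with replacement from genes of the same decile of the number of coding TSS within 100 kb. They do not copy the closeness of clustered genes such as Hox. The 18 lists, the motifs, the main settings and the rule for named genes were set before the data were examined: in each list the 4 genes with the most covered kb and the 2 with the least (ties in order of symbol), the 20 most covered genes with 1 per 100 kb, the genes of the 20 largest domains and the 10 peaks of highest fold, and all Hox genes. From the receptor list and for some low members only a summary is given. The thresholds of percentiles 97.5 and 2.5 were set once the peak lists had been opened but before any gene list was computed. The summary over replicates was settled after a first version, the median of each gene's mean, had been seen; that version is kept as an alternative. The symbol Drgx was not in the annotation and was left out of the neuronal subtype list.

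Motifs were matched exactly on both strands, with the reversed, uncomplemented sequence as a control of base composition, and ratios carry 95% intervals from the counts. Reversal keeps the bases but not their neighbours. It adds a CpG to the CAGCTG, POU, NFI, RFX and CTCF motifs and takes it from the ETS motif, so these contrasts can also reflect CpG content. No test between groups was possible with 1 group, and peaks and genes are not replicates, so no p-value was computed. Alternatives covered the overlap rule, a −log10 q of at least 5, the list used, the windows, the random lists, the background and leaving out each replicate. Lists without genes of the X and random lists matched on promoter CpG content were added after seeing the data, as was the share of receptor genes with no peak among CpG-matched lists. The code was tested on simulated data. Of 20000 simulated peaks with 39.8% planted as shared, 39.8% were recovered. Of 200 random lists of 24 genes 4% were called with nothing planted, and 88% were called high with covered kb raised 3-fold, over 21728 genes. In 4000 random sequences with a motif planted in 19.5%, it was found in 19.7%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.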

Results

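Monomethylation of lysine 4 on histone H3 (H3K4me1), a modification known to lie over enhancers and beside active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos at embryonic day 11.5. The neural tube is the embryonic structure that gives rise to the brain and spinal cord. There was 1 group with 2 biological replicates, pools of 109 embryos (replicate 1) and 88 embryos (replicate 2) of the strain B6NCrl, with both sexes mixed in each pool. The data were peak lists on the mouse assembly mm10, which is GRCm38, so the number of reads behind each peak was unknown. Replicate 1 had 124896 peaks covering 46.8 Mb, or 1.83% of the sequenced bases, and replicate 2 had 106333 peaks covering 40.1 Mb, or 1.57%. The median peak was 278 bp wide in replicate 1 and 287 bp in replicate 2. A list called on both replicates together held 81261 peaks, and a list of replicated peaks held 62956. No other tissue, age or treatment was present, so the comparisons were between the replicates, between classes of sequence, between chromosomes and between lists of genes set before the data were examined. With 2 replicates in 1 group no p-value was computed; errors are SDs of the replicates.

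The replicates were compared peak by peak to find which part of the map was shared. Of the replicate 1 peaks, 43.5% shared a peak with replicate 2 (Wilson 95% interval 43.3 to 43.8, which covers counting error only), where 50% of either peak had to overlap. Of the replicate 2 peaks, 51.8% were shared (51.5 to 52.1). After random circular shifts of the positions the shares were 2.18% and 2.55%, so the observed overlap was 20.02 and 20.3 times that of shifted positions. The shared share followed the fold enrichment that the authors' peak caller gave each peak. In the decile with the highest fold, 86.3% of replicate 1 peaks and 90.4% of replicate 2 peaks were shared, against 26.0% and 34.9% in the lowest decile. Shared peaks were wider than unshared ones, with medians of 390 and 238 bp in replicate 1 and of 368 and 244 bp in replicate 2. Within the shared peaks the order of fold enrichment matched only in part: Spearman's rho was 0.274 across 58839 pairs of peaks, which are not independent replicates. A different quantity, the kb inside peaks within 50 kb of the transcription start site (TSS) of 21728 protein coding genes, had a rho of 0.960 across genes, whose windows overlap and of which 18.3% had none in both replicates. The share of shared peaks ran from 26.8% to 60.3% over the other overlap rules, and a peak threshold of −log10 q of at least 5 gave 34.4% of replicate 1 peaks and 49.0% of replicate 2 peaks.

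**Figure D1:**
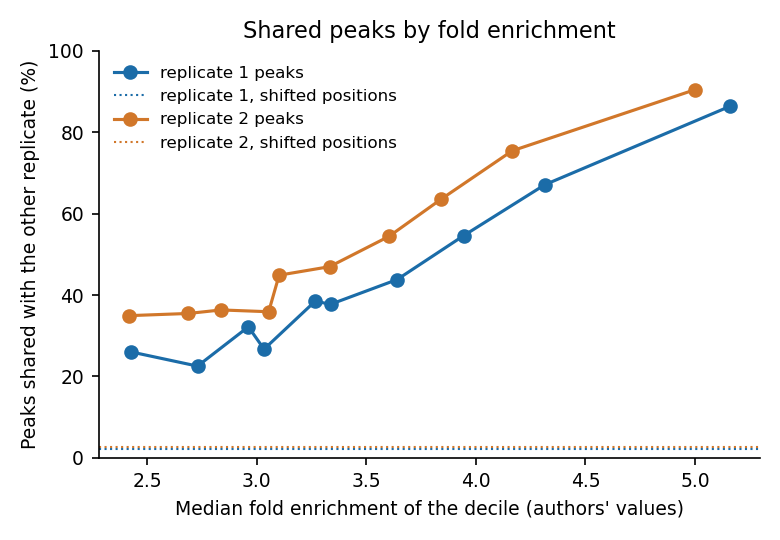
Percent of each replicate's peaks shared with the other replicate (vertical axis) in deciles of the authors' fold enrichment (horizontal axis, median of the decile), with the mean share after shifting positions as dotted lines. The share rises to 86.3% and 90.4% in the top decile, while shifted positions give 2.18% and 2.55%.

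The list called on both replicates was set beside the single replicates. All 62956 replicated peaks were in that list, 77.5% of its 81261 peaks. By the 50% rule 66.1% of its peaks had a partner in both replicates, 19.6% in replicate 1 alone, 13.6% in replicate 2 alone and 0.748% in neither. The 18305 peaks left out of the replicated list were narrower than those kept (median 228 against 384 bp) and had a lower fold (2.79 against 3.33). The joint list had fewer peaks than either replicate: 96.9% of the replicate 1 peaks that were shared overlapped a peak of it, but 30.0% of the unshared peaks of replicate 1 and 31.5% of those of replicate 2 did. Only 47.2% of its peaks had a partner in both replicates when 50% of both peaks had to overlap.

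H3K4me1 peaks were concentrated near genes. Peak midpoints within 1 kb of a coding TSS made up 10.3% ± 0.453 of peaks (SD, n = 2), 6.47 ± 0.283 times the share of sequenced bases there. A further 23.3% ± 0.125 lay 1 to 10 kb from a TSS, 1.87 times the share of bases, and 40.5% ± 0.273 lay elsewhere inside genes, 1.24 times. Intergenic sequence held 25.9% ± 0.305 of the midpoints, 0.487 ± 0.00573 times its share of bases. Each of these ratios differed from 1 by more than 10 times the SD of the replicates.

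Around the TSS itself the peaks left a dip. In the 100 bp steps centred up to 150 bp from the TSS, 7.12% ± 0.164 of positions lay in a peak (SD, n = 2). At 1 to 2 kb it was 10.7% ± 1.37, a ratio of 0.675 ± 0.102. The flanks were unequal. At 1 to 2 kb downstream 15.6% ± 1.97 of positions were covered and at the same distance upstream 5.70% ± 0.775. The mean of the replicates was highest 950 bp downstream, at 20.6%, and at 9 to 10 kb it was 2.57% ± 0.163. The dip was deeper among peaks with a −log10 q of at least 5, where the ratio was 0.327.

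**Figure D2:**
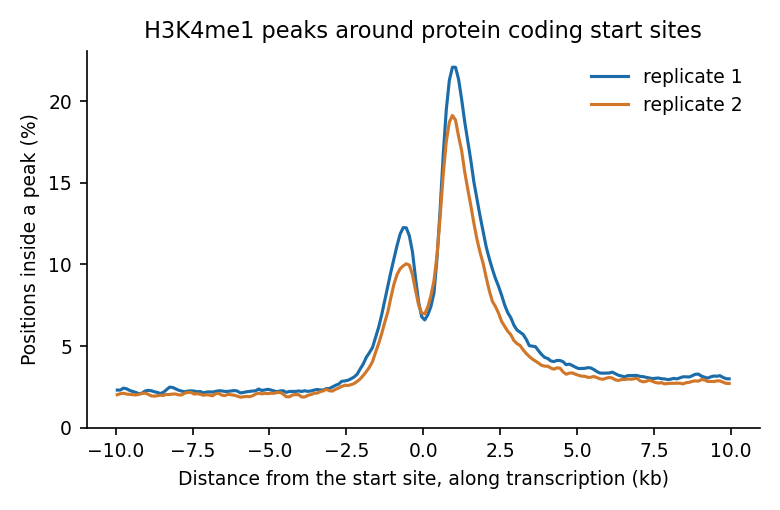
Percent of positions inside an H3K4me1 peak (vertical axis) by distance from the TSS of 21728 protein coding genes along the direction of transcription (horizontal axis, kb), 1 line per replicate. Both lines dip at the TSS and reach their highest values about 1 kb downstream, where the mean is 20.6%.

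Coverage was compared between chromosomes because embryos of both sexes were pooled. Chromosome 11, which holds the HoxB cluster, was the most covered, with 3.17% ± 0.247 of its sequenced bases in peaks (SD, n = 2), and chromosome 3 the least covered autosome, with 1.19% ± 0.188. The X chromosome stood far below all 19 autosomes at 0.106% ± 0.0373. It held 745 of the replicate 1 peaks, 448 of the replicate 2 peaks and 178 of the replicated peaks. Its ratio to the median autosome was 0.0579 ± 0.0156, 0.0315 in the replicated list, 0.0263 with equal numbers of the strongest peaks and 0.00940 among peaks with a −log10 q of at least 5. Of 948 coding genes on the X, 58.9% had no peak within 50 kb in either replicate, against 16.4% of autosomal genes. Of the genes of the X in the neural, crest and glia lists, 3 were the least covered of their list: Sox3, a transcription factor of neural progenitors (0.478 ± 0.379 kb), Arx, a homeobox gene of the floor plate and interneurons (0.376 ± 0.263 kb), and Plp1, a myelin gene (0 kb). The other 2, both pan-neuronal, were Syp, a synaptic vesicle gene, with 0.530 ± 0.190 kb at rank 22 of 24, and Dcx, a gene of newborn neurons, with 1.11 ± 0.601 kb at rank 17.

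**Figure D3:**
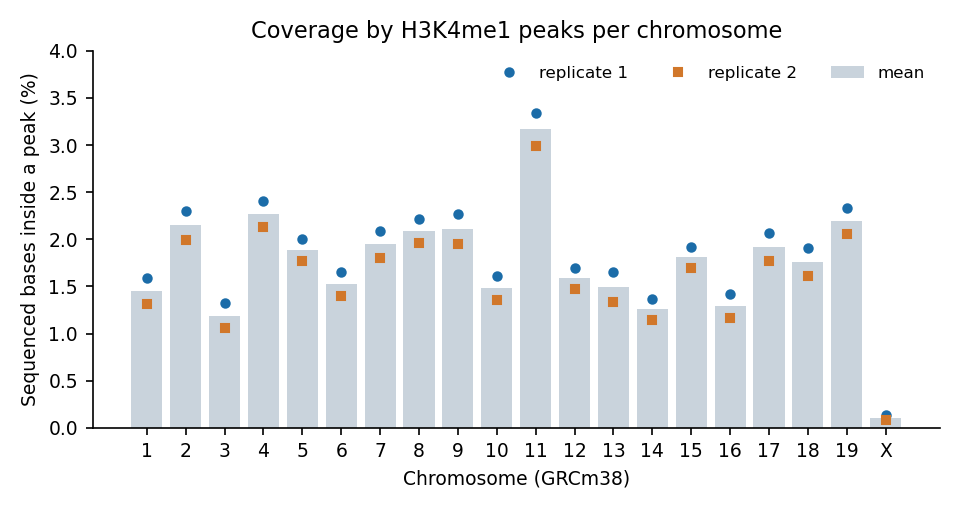
Percent of sequenced bases inside H3K4me1 peaks (vertical axis) on each chromosome (horizontal axis), with the mean of the replicates as bars and each replicate as a point. The X lies at 0.106%, while autosomes run from 1.19% (chromosome 3) to 3.17% (chromosome 11).

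Gene neighbourhoods were compared by list. For each list the kb inside peaks within 50 kb of the TSS were taken per gene, and the list's median was placed among 10000 random lists of the same size matched on the number of neighbouring genes. The median over all coding genes was 1.70 ± 0.255 kb (SD, n = 2), and 18.3% of genes had none. A list above the central 95% of random lists is called high and one below it low. Percentiles describe these libraries and are no test across embryos.

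Genes of neural progenitors, the dividing cells of the neural tube, had the highest median of the fixed lists other than Hox. The median of the 24 genes was 9.13 ± 0.120 kb (SD, n = 2), above all 10000 random lists, whose median was 1.29 kb. Of these genes 22 lay above the genome median and 13 in the genome's top decile. Notch1, the receptor that keeps progenitors undifferentiated, had 35.3 ± 2.84 kb (chromosome 2, 26457903 to 26516663). Nes, which encodes the intermediate filament nestin, had 23.1 ± 1.63 kb (chromosome 3, 87971078 to 87980451), the RNA-binding protein gene Msi1 had 14.3 ± 1.39 kb (chromosome 5, 115429599 to 115455698) and the Notch target Hes5 had 13.8 ± 0.177 kb (chromosome 4, 154960923 to 154962371). Prom1, with 1.20 ± 0.0700 kb, and Sox3 were lowest.

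Genes that pattern the tube from back to belly had a median of 5.28 ± 0.0983 kb (SD, n = 2; 31 genes), again above all random lists, and 27 lay above the genome median. The highest were the dorsal paired-box genes Pax7 (21.6 ± 0.838 kb; chromosome 4, 139737062 to 139833528) and Pax3 (13.5 ± 4.799 kb), the Sonic hedgehog receptor Ptch1 (21.2 ± 2.18 kb; chromosome 13, 63508328 to 63573598) and the roof plate and dorsal interneuron gene Lmx1b (15.6 ± 1.94 kb). Nkx2-9, a gene of ventral progenitors, was low at 0.456 ± 0.0346 kb, as was Arx. Transcription factors of neuronal subtypes had a median of 3.70 ± 0.269 kb (35 genes), above all random lists, with 33 genes above the genome median. Ebf3 (20.2 ± 3.41 kb; chromosome 7, 137193673 to 137314445) and Ebf1 (12.48 ± 2.02 kb), which act in newborn neurons, the sensory neurogenic factor Neurog1 (14.5 ± 1.49 kb) and the interneuron gene Pax2 (9.77 ± 1.11 kb) led this list. Isl1, a motor neuron gene, had 0.549 ± 0.226 kb and Bhlhe22 0.614 ± 0.255 kb.

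The pan-neuronal list held genes shared by most neurons and transmitter genes of some neurons only (Slc17a6, Gad1, Gad2, Slc32a1, Chat and Slc18a3). It fell just short of the threshold, with a median of 2.41 ± 0.477 kb (SD, n = 2, 24 genes) at percentile 97.0. Of its genes 15 lay above the genome median. Rbfox3, which encodes the neuronal nuclear antigen NeuN, had 11.7 ± 0.124 kb and the RNA-binding protein gene Elavl3 6.98 ± 0.801 kb. Ncam1 had 5.94 ± 2.69 kb and the neurofilament gene Nefl 5.92 ± 1.74 kb. The synaptic genes Syt1 (0.1 ± 0.141 kb) and Nrxn1 (0.195 ± 0.00707 kb) were nearly free of peaks. The list passed with replicate 1 alone, at percentile 97.55, and without the genes of the X, at 98.6, but under the other alternatives it lay between 82.9 (unmatched random lists) and 97.2, apart from peaks with a −log10 q of at least 5, where its median and that of random lists were both 0.

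Genes of the rostral brain, which are mostly used ahead of the spinal cord and hindbrain, had a median of 2.74 ± 0.161 kb (SD, n = 2; 25 genes) at percentile 99.6, with 19 above the genome median but 1 in the top decile. Dmbx1 (10.02 ± 0.588 kb), the neighbouring genes Dlx2 (6.53 ± 1.56 kb) and Dlx1 (6.46 ± 1.36 kb), and Emx2 (4.47 ± 0.335 kb) were highest. Foxg1, the forebrain regulator, had 0.546 ± 0.771 kb and Nkx2-1 0.734 ± 0.406 kb. Among peaks with a −log10 q of at least 5 the list's median and that of random lists were both 0, which decides nothing, and the call was lost with unmatched random lists (91.1), a 100 kb window (96.4) and random lists matched on CpG content (96.5). Replicate 1 covered 0.922 times as many kb around these genes as replicate 2, against 1.12 times around all coding genes, which placed the rostral list at percentile 0.05 of random lists for this ratio.

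Lists of other cell types in or beside the neural tube were measured in the same way. Genes of neural crest, the migratory cells that leave the dorsal tube, and of glia had a median of 2.99 ± 0.484 kb (SD, n = 2; 22 genes; percentile 99.0), led by the neurotrophin receptor Ngfr (18.7 ± 3.27 kb), Sox8 (12.2 ± 0.928 kb), Sox10 (9.17 ± 0.372 kb) and Ntrk1 (8.71 ± 0.798 kb), while Snai2 had 0.0950 ± 0.134 kb. This call was lost under 4 of the alternatives, with percentiles down to 93.8. Genes of sclerotome and mesenchyme, the tissue next to the tube, had 4.78 ± 0.00849 kb (24 genes), above all random lists. Col2a1 (14.5 ± 0.404 kb; chromosome 15, 97975602 to 98004695), the collagen gene of cartilage and notochord, Tcf15 (11.98 ± 1.07 kb), Prrx2 (11.3 ± 0.374 kb) and Uncx (10.003 ± 1.55 kb), a homeobox gene of the somites that is also used in the neural tube, were highest, and Runx2 (0.650 ± 0.919 kb) and Meox2 (0.809 ± 0.0431 kb) lowest. Endothelial genes did not stand apart (2.16 ± 0.171 kb; percentile 65.3). Egfl7, the highest of them with 12.3 ± 1.10 kb, lies beside Notch1, Eng had 11.03 ± 1.54 kb, Ramp2 10.1 ± 0.369 kb and Fli1 9.43 ± 1.30 kb, and Tek had none.

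Lists of tissues other than the nervous system were mostly unremarkable. Erythroid genes had the lowest median among the lists of 20 genes, 1.15 ± 0.110 kb (SD, n = 2; percentile 5.34), and were called low with a 20 kb window (percentile 1.49) or the replicated list (1.12). Against random lists matched on CpG content, which is low at these genes, they lay on the other side of the median, at percentile 71.7. Nfe2 (21.7 ± 2.08 kb), Slc4a1 (8.17 ± 1.01 kb), Klf1 (7.60 ± 0.423 kb) and Epor (5.04 ± 0.482 kb) were exceptions, and the embryonic globin gene Hbb-y and the spectrin gene Spta1 had none. Macrophage and immune genes had 2.87 ± 0.192 kb (percentile 76.1, and 93.3 with CpG matching), with Cd68 at 7.98 ± 0.537 kb and Mrc1 and Itgam at 0. Hepatocyte genes had 1.34 ± 0.131 kb (percentile 27.9, 1.87 with a 20 kb window and 57.4 with CpG matching), with Apoa2 at 8.43 ± 1.01 kb and Cyp7a1 and Serpina1a at 0. Cardiac genes had 2.44 ± 0.295 kb (percentile 86.1, and 93.2 with CpG matching), with Myl7 at 8.24 ± 1.33 kb and Smyd1 at 0.214 ± 0.00636 kb. Skeletal muscle genes were called high, at 3.46 ± 0.728 kb and percentile 98.2. Tnnt3 (21.2 ± 1.17 kb), Tnni2 (8.61 ± 0.554 kb), whose window overlaps that of Tnnt3, Des (11.8 ± 2.04 kb) and Cdh15 (7.92 ± 0.398 kb) led that list, while Ttn had none. The call was lost without replicate 1, at percentile 96.3, with unmatched random lists, at 97.1, and among peaks with a −log10 q of at least 5, at 83.7. It was kept with CpG matching, at 99.4, and with a 20 kb window, at 99.3. Housekeeping genes had 3.86 ± 0.332 kb (27 genes; percentile 99.1), led by Hsp90ab1 (13.1 ± 0.421 kb), Rplp0, Eef2 and Rps18, but fell to percentile 87.9 against random lists matched on the CpG content of promoters. Of 1464 olfactory and vomeronasal receptor genes, which are used in sensory neurons of the nose, 1293 had no peak within 50 kb, and the list's median of 0 kb was below all 1000 random lists. Against random lists matched on CpG content, which is low at these genes, the median could not be compared, since both were 0, but 88.3% of the receptor genes had no peak against 60.3% in those lists (at most 63.9% in 1000 lists).

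**Figure D4:**
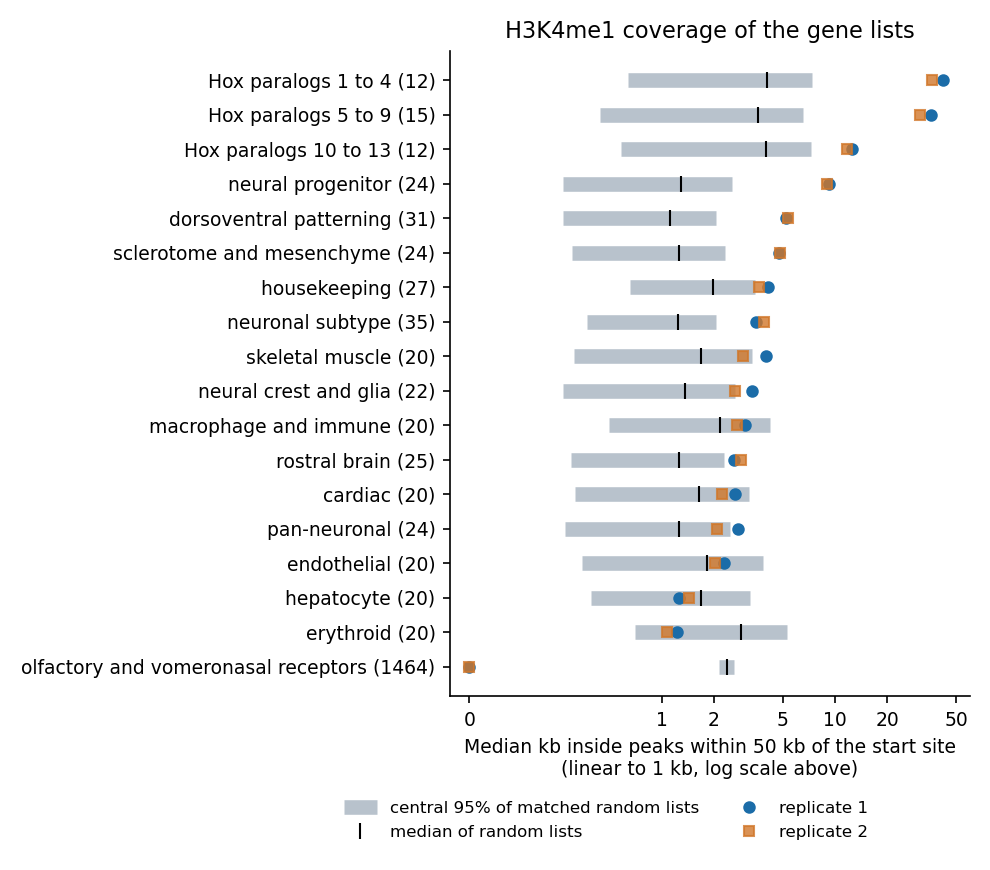
Median kb inside H3K4me1 peaks within 50 kb of the TSS (horizontal axis, linear to 1 kb and logarithmic above) for each list, with the number of genes in brackets, each replicate as a point, and the central 95% and the median of matched random lists as a bar and a tick. The Hox, neural progenitor and dorsoventral lists lie to the right of their bars in both replicates, at 39.3, 33.3, 12.1, 9.13 and 5.28 kb on average. The sclerotome and mesenchyme list does so too, at 4.78 kb.

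Set against each other, the pooled neural lists (progenitor, dorsoventral, subtype and pan-neuronal) had a median of 4.04 ± 0.0223 kb and the pooled lists of other tissues (erythroid, immune, skeletal muscle, hepatocyte and cardiac) 1.92 ± 0.119 kb. The difference of 2.12 ± 0.0965 kb (SD, n = 2) exceeded that of all 10000 pairs of random lists. These pairs were not matched on the kind of gene, such as transcription factors. The difference can therefore follow the kind of gene as well as the tissue. The endothelial, mesenchymal and neural crest lists were left out of the pool of other tissues, since dissections of the neural tube can hold these cells. Of these, the mesenchymal median (4.78 kb) was above the pooled neural median, and the neural crest (2.99 kb) and endothelial medians (2.16 kb) were below it. The neural progenitor list exceeded each of the 5 lists in the pool of other tissues, by 5.67 ± 0.608 kb (skeletal muscle) to 7.98 ± 0.0103 kb (erythroid). The dorsoventral list did so too, from 1.81 ± 0.826 kb (skeletal muscle) to 4.12 ± 0.208 kb (erythroid). The neuronal subtype list was above 4 of the lists and differed from the skeletal muscle list by 0.236 ± 0.997 kb, less than the spread of the replicates. The pan-neuronal list was above the erythroid list (1.26 ± 0.367 kb; percentile 99.4) and stood apart from none of the other 4. Promoters of the neural lists are richer in CpG, and with random lists matched on it the pooled difference kept percentile 100 and the progenitor and dorsoventral lists kept their calls (lowest percentile 97.8). The pan-neuronal list then no longer stood above the erythroid list (83.5), nor the neuronal subtype list above the immune (76.8) and cardiac lists (89.8).

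The Hox genes, which encode position along the body axis and lie in 4 clusters, included the coding genes with the most covered kb. Their mean coverage fell from the front to the last group of paralogs, though not gene by gene within a cluster. Of each gene and 2 kb either side, peaks covered 47.3% ± 3.33 on average for paralogs 1 to 4 (SD, n = 2; 12 genes), 33.4% ± 6.41 for paralogs 5 to 9 (15 genes) and 7.16% ± 1.09 for paralogs 10 to 13 (12 genes). The mean of all coding genes was 4.66% ± 0.350. The step to paralogs 10 to 13 was several times the SD. The step between the anterior groups was 2 to 4 times it. In the HoxA cluster on chromosome 6 coverage was 62.9% ± 2.72 at Hoxa4 (52189671 to 52191753), 62.8% ± 3.69 at Hoxa5 and 63.6% ± 14.9 at Hoxa6, then 31.8% ± 3.59 at Hoxa7, 10.7% ± 9.64 at Hoxa9 and 8.05% ± 3.22 at Hoxa11. Hoxa1 had 52.3% ± 0.483, Hoxa2 34.3% ± 7.31, Hoxa3 64.4% ± 5.79, Hoxa10 11.4% ± 4.17 and Hoxa13 14.1% ± 6.23. In HoxB on chromosome 11, Hoxb3 was covered over 70.5% ± 3.16 (96323326 to 96347930), the most of all Hox genes. Hoxb1 and Hoxb2 had 38.6% ± 2.73 and 32.3% ± 4.85, Hoxb4 25.4% ± 0.0863, Hoxb5 35.2% ± 18.1, Hoxb6 27.2% ± 13.95, Hoxb7 31.4% ± 2.51 and Hoxb8 16.1% ± 0.334. Hoxb9 still had 35.4% ± 3.74, and the distant Hoxb13 had 5.31% ± 0.406.

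In HoxC on chromosome 15 coverage was 59.7% ± 3.57 at Hoxc4 (103018934 to 103036852), 32.8% ± 3.39 at Hoxc5, 44.1% ± 2.52 at Hoxc6, 37.2% ± 15.5 at Hoxc8 and 20.3% ± 1.78 at Hoxc9 (SD, n = 2). Hoxc10 and Hoxc11 had 2.54% ± 3.598 and 3.17% ± 4.48, each with no coverage in replicate 1, and Hoxc12 and Hoxc13 had 9.69% ± 2.05 and 2.89% ± 1.44. In HoxD on chromosome 2 Hoxd1 had 17.7% ± 6.06, Hoxd3 59.7% ± 8.05, Hoxd4 50.3% ± 6.26, Hoxd8 36.4% ± 4.98 and Hoxd9 16.4% ± 2.61. Hoxd10 had 10.5% ± 4.16, Hoxd11 2.56% ± 3.62, Hoxd12 4.06% ± 1.07 and Hoxd13 11.7% ± 4.40. Among peaks with a −log10 q of at least 5 the means were 22.5%, 7.65% and 0% for the groups from front to back. By kb within 50 kb of the TSS the lists had medians of 39.3 ± 4.20, 33.3 ± 3.47 and 12.1 ± 0.531 kb, with Hoxb13 (2.32 kb) and Hoxc13 (1.83 kb) lowest. These windows take in neighbouring Hox genes, and with a window of 20 kb paralogs 10 to 13 fell from above all random lists to percentile 90.7. The annotated spans of Hoxa3, Hoxc5, Hoxd3 and Hoxd4 run across neighbouring Hox genes, so their values are not independent.

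**Figure D5:**
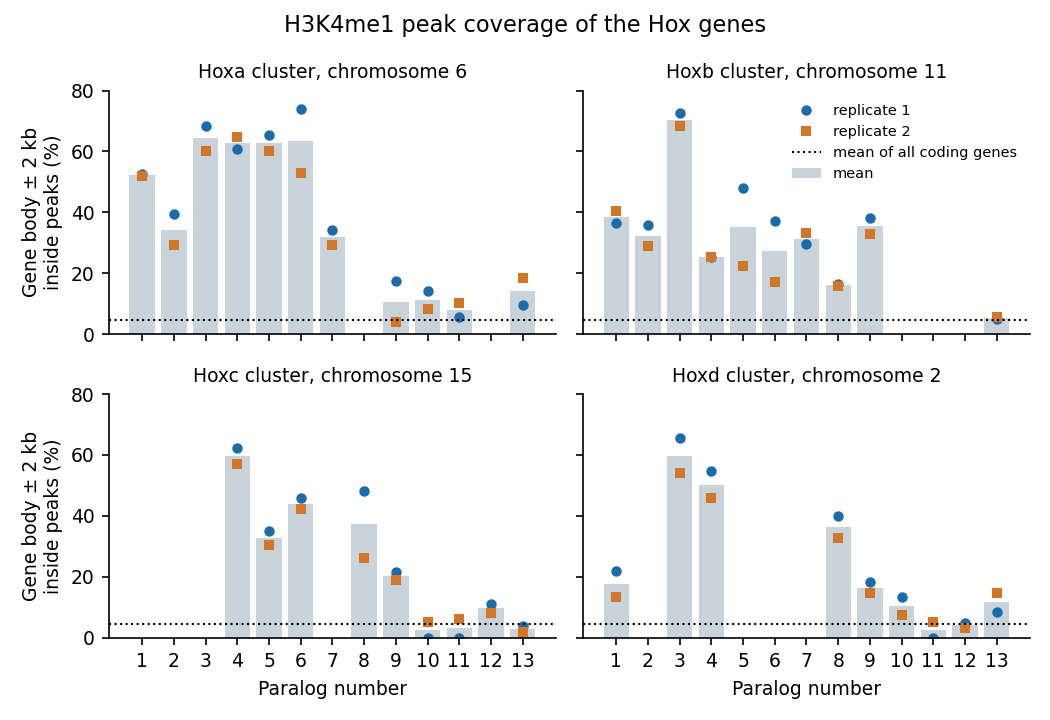
Percent of each Hox gene and 2 kb either side inside H3K4me1 peaks (vertical axis) by paralog number (horizontal axis), 1 panel per cluster, with the mean of the replicates as bars, each replicate as a point and the mean of all coding genes (4.66%) as a dotted line. Coverage falls toward paralogs 10 to 13, which average 7.16%, from 47.3% at paralogs 1 to 4.

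The most covered gene neighbourhoods were in and outside the Hox clusters. Taking 1 gene per locus, the 20 genes with the most covered kb were led by Hoxb5 (47.2 ± 3.13 kb), Hoxc4 (46.0 ± 4.59 kb) and Hoxa4 (44.2 ± 4.99 kb), with Hoxd8 (33.8 ± 4.18 kb) in place 9. Ncor2, a nuclear receptor corepressor, followed with 39.2 ± 1.15 kb (SD, n = 2; chromosome 5, 125017153 to 125179219), then Ccdc85c with 38.9 ± 1.35 kb (chromosome 12, 108203602 to 108275425), Bahcc1 with 36.4 ± 1.46 kb and Notch1. Cxxc5 had 34.8 ± 0.484 kb and Igdcc3 32.8 ± 0.709 kb. Rara, a retinoic acid receptor, had 32.6 ± 0.4002 kb (chromosome 11, 98927818 to 98974942), and the Groucho-family corepressor Tle3 had 32.3 ± 2.23 kb. The rest were Flrt1, Gse1, Pmepa1, Ski, Ssbp3, Ahdc1, Zmiz1 and Zfp608, from 32.2 ± 1.05 down to 29.6 ± 1.92 kb.

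Replicated peaks no more than 5 kb apart were joined into 29058 domains, of which 15317 were single peaks. The domain with the most covered bases spanned 135 kb of chromosome 8 (120436255 to 120571651) inside Gse1, with 85.7 kb in 72 peaks, and the next, also inside Gse1 (120332529 to 120429186), had 58.6 kb in 50 peaks. A domain inside Msi2, a neural RNA-binding protein gene (chromosome 11, 88515422 to 88631513), had 55.9 kb and one inside Ssbp3 (chromosome 4, 106932401 to 107003982) 49.4 kb. The HoxA domain from Hoxa1 to Hoxa7 (chromosome 6, 52150262 to 52222356) had 39.0 kb. Domains at Ccdc85c, Ncor2, Cxxc5, Pmepa1, Zfhx3, Igdcc3, Bahcc1, Hoxb2 to Hoxb5, Zmiz1, Ski, Hoxd3 and Hoxd4, Hoxc4, Notch1, Sept9 and Zfp608 completed the 20 largest, down to 24.6 kb. Of the 114 genes of the pooled neural lists 6 had a TSS within 50 kb of the 200 largest domains, 5.26% against 1.505% in random lists (percentile 99.5), while 2 of the 100 genes of other tissues did (percentile 50.1). The neural progenitor list had 3 of 24 genes there (percentile 99.6), but lost this call without replicate 2 (percentile 80.8) and with the widest joining distance (94.8). The dorsoventral list had 2 of 31 (percentile 95.8), and passed without either replicate (99.3 in each case) and with the narrower or wider joining distance (99.6 and 98.8), but not among peaks with a −log10 q of at least 5 (1 of 31, percentile 83.4). All 27 Hox genes of paralogs 1 to 9 were near such a domain (12 and 15). No mesenchymal, endothelial, immune, hepatocyte, cardiac, housekeeping or pan-neuronal gene of the lists lay near such a domain, where random lists of these sizes had 1.28% to 2.39% of their genes. Without replicate 1, 2 of 24 mesenchymal genes (percentile 97.2) and 1 of 20 immune genes did, and without replicate 2, 1 of each.

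The 10 replicated peaks with the highest fold enrichment, as the authors' caller gave it, all had their summits in introns. The highest, at 9.04-fold, lay in Gse1 (chromosome 8, 120496736 to 120499574) and a further one in the same gene (120510411 to 120515613) had 8.23-fold. Next to it ranked peaks in Ncor2 (chromosome 5, 125139967 to 125143113, 8.86-fold), Klf3 (chromosome 5, 64810143 to 64813054, 8.52-fold), Tmem94 (chromosome 11, 115779571 to 115781557, 8.50-fold), Ndst1 (chromosome 18, 60734677 to 60736910, 8.42-fold) and Ahdc1 (chromosome 4, 133020239 to 133026347, 8.36-fold). Peaks in Rara (chromosome 11, 98969541 to 98971917, 8.23-fold), Cuedc1 (chromosome 11, 88159933 to 88161318, 8.13-fold) and Rere (chromosome 4, 150567930 to 150569343, 8.13-fold) followed. The gene with the nearest TSS was another one for the peaks in Gse1 (Gins2), Ndst1 (Rps14), Rara (Gjd3), Cuedc1 (Mrps23) and Rere (Slc45a1).

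Short binding motifs were counted in 500 bp around the summits of 54880 replicated peaks over 1 kb from any TSS and in 77871 pieces 3 kb away outside all peaks. The E-box CAGCTG, which proneural factors such as Ascl1 bind, was found in 33.1% of peaks and 21.4% of background pieces, a ratio of 1.55 (95% interval 1.52 to 1.58, for counting error only) against 1.14 for its reversed sequence. The CAGATG E-box had a ratio of 1.08 (1.07 to 1.10) and its reversed sequence 0.663. The HOX-PBX site TGATTTAT had a ratio of 1.26 (1.18 to 1.34) against 0.702 for its reversed sequence, and the POU octamer ATGCAAAT 1.17 (1.10 to 1.25) against 0.797. RFX (1.30), NFI (1.11), TEAD (1.10), CTCF (1.80) and ETS (1.53) motifs were also above 1. The reversed CTCF and NFI sequences had ratios of 1.87 and 1.26, higher than the motifs themselves, and the reversed RFX sequence had 1.23, with an interval (1.10 to 1.37) that held the motif's ratio. Those of TEAD and ETS had 1.01 and 1.11. The A and T rich motifs of SOX (0.911), homeodomain (0.923) and GATA factors (0.866) were below 1, and HNF4 (1.03) and MEF2 (1.07) had intervals that included 1. Peaks held more G and C than the background (49.4% against 45.6%). With background matched on GC share the ratio of the HOX-PBX site was 1.94 against 1.11 for its reversed sequence, that of the POU octamer 1.57 against 1.08 and that of the CAGCTG E-box 1.27 against 0.957. The SOX, homeodomain and GATA motifs turned to 1.21, 1.40 and 1.09, but their reversed sequences gave 1.15, 1.39 and 1.07, close to the motifs themselves. The POU ratio was 0.993 in windows of 200 bp, against 0.661 for its reversed sequence, and among peaks with a −log10 q of at least 5 the intervals of the POU (1.26, reversed 0.860), HOX-PBX (1.22, reversed 0.561) and ETS (0.819, reversed 1.22) ratios included 1, as did that of ETS with matched background (1.28).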

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

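Of 436 recomputed values for 85 results, 367 stayed on the same side of their threshold or within the spread of the replicates. Overlaps and rho were instead held to a counting interval or a fixed tolerance. Lists with no call under either setting count as unchanged. Of the 68 values outside the single gene lists, domains and motifs, 36 stayed and 32 moved. The alternatives without X genes, with CpG matching and with the median of each gene's mean were chosen after seeing the data. The cause was not tested for the changes below, except where the rule itself sets the share. Shared peaks of replicate 1 and 2 were 51.3% and 60.3% with 1 bp of overlap, 26.8% and 31.5% with 50% of both peaks, 34.4% and 49.0% at a −log10 q of at least 5 (Jaccard index 0.270), and 47.0% and 48.3% with equal numbers of the strongest peaks. Rho of fold was 0.252, 0.391, 0.232 and, for −log10 p, 0.295. Peaks of the joint list found in both replicates were 69.3% (1 bp), 47.2% (50% of both) and 67.2% (strict). Promoter enrichment was 7.92 in the replicated list, 7.58 strict, 5.22 within 500 bp and 5.75 within 2 kb, and intergenic 0.440 and 0.359 in the former pair. The TSS ratio was 0.570 (replicated), 0.327 (strict) and 0.819 (all annotated genes), and the X ratio 0.0315 (replicated), 0.00940 (strict) and 0.0263 (equal numbers).

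Gene list percentiles changed side as follows. The pan-neuronal list rose to 98.6 without X genes, and ran from 95.4 to 97.55 when a replicate was left out. The rostral brain list fell to 96.4 (100 kb window), 91.1 (unmatched) and 96.5 (CpG); its strict value of 45.3 is a tie of medians at 0 that decides nothing. Hox paralogs 10 to 13 fell to 90.7 (20 kb). Neural crest and glia fell to 96.4 (20 kb), 96.6 (100 kb), 93.8 (unmatched) and 95.6 (strict). Erythroid went to 1.49 (20 kb) and 1.12 (replicated), and hepatocyte to 1.87 (20 kb). Skeletal muscle fell to 97.1 (unmatched) and 83.7 (strict) and ran from 96.3 to 98.8 with a replicate left out. With CpG matching, housekeeping fell to 87.9 and the receptor list went to 50, likewise a tie. No other gene list call changed under the alternatives run, and neural against non-neural lists kept its call under each of them, CpG matching included. CpG matching was the only alternative run for differences between single lists. Strict peaks covered 22.5%, 7.65% and 0% of the Hox groups, and replicated peaks 4.92% of paralogs 10 to 13. Motif ratios with GC matching were 1.21 (SOX), 1.40 (homeodomain), 1.09 (GATA) and 1.28 (ETS); strict peaks gave 0.920 (SOX), 1.26 (POU), 1.22 (HOX-PBX) and 0.819 (ETS), with fewer peaks and wider intervals. The homeodomain motif had 0.981 in 1 kb windows, POU 0.993 and ETS 1.54 in 200 bp windows, and ETS 1.21 with background 10 kb away. Depth was unknown, so the absence of a peak shows no absence of the mark.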

Other observations

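Genes of the signalling pathways that pattern the neural tube were covered more than random lists. These lists were drawn up after the most covered genes had been seen, so they are not independent of them, and the genes named here were chosen after their values were seen. The Notch, Hedgehog and Wnt lists also repeat genes of the fixed lists. Notch1, Hes1, Hes5, Dll1, Dll3 and Gli3 are in the progenitor list, and Ptch1, Gli1, Gli2, Shh, Wnt1 and Wnt3a in the dorsoventral list. The window of the retinoic acid gene Crabp2 overlaps that of the progenitor gene Nes. Against random lists matched on the CpG content of promoters as well, the signalling, axon guidance and corepressor lists had percentiles from 99.92 to 100. Notch pathway genes had a median of 7.90 ± 0.474 kb inside peaks within 50 kb of the TSS (SD, n = 2; percentile 100; 22 of 22 above the genome median). Retinoic acid genes had 6.24 ± 0.562 kb (percentile 100; 14 of 18), from the receptor Rara (32.6 kb), the binding protein Crabp2 (25.2 ± 1.27 kb) and the retinol transporter Stra6 (17.7 ± 0.670 kb) down to the 4 below the genome median, the receptors Rarb (1.47 ± 0.238 kb) and Rxrg (1.35 ± 0.450 kb) and the synthesising enzymes Aldh1a2 (1.31 ± 0.2998 kb) and Aldh1a1 (0.387 ± 0.205 kb). Hedgehog genes had 6.27 ± 0.539 kb (percentile 100; 16 of 16), led by the co-receptor Boc (23.99 ± 2.13 kb), and canonical Wnt genes 5.22 ± 0.273 kb (percentile 99.99; 23 of 24), led by the Wnt target Axin2 (17.4 ± 0.252 kb). Axon guidance receptors had 4.09 ± 0.513 kb (percentile 99.99; 18 of 22), with Ephb2 at 21.6 ± 0.776 kb and Robo1 at 0.136 ± 0.192 kb. Transcriptional corepressors had 6.68 ± 0.575 kb (percentile 100; 21 of 27), but this list holds genes picked from the most covered ones. Genes of synaptic ion channels had 0.685 ± 0.134 kb (percentile 15.4; 5 of 23 above the genome median), which did not stand apart from random lists.

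Among 355 families of at least 8 genes grouped by symbol after the data were seen, 54 lay above and 56 below the central 95% of random lists. Many families lie at 1 locus and share windows, which random lists do not copy, so these counts cannot be set against chance. The Cbx genes (8 genes), which encode chromobox proteins, had a median of 11.3 ± 1.29 kb (SD, n = 2), genes of the Arid family, which share a DNA-binding domain, 6.55 ± 1.30 kb (10 genes), the splicing factors of the Srsf family 6.48 ± 1.13 kb (11 genes), the Wnt ligands 6.34 ± 0.263 kb (19 genes) and the semaphorins 6.15 ± 0.700 kb (20 genes). The clustered protocadherins, adhesion proteins of neurons, were low: all 11 genes of the Pcdha family and all 22 of the Pcdhb family had no peak within 50 kb, and the 12 of the Pcdhga family had a median of 0.106 ± 0.150 kb, against 5.17 kb in random lists. Members of a cluster share windows, so their counts are not independent. Keratins were also low (0.901 ± 0.0417 kb; 53 genes).

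The tests of cell mixture in the mesenchymal list, and those on the joint list, were chosen only after the results had been seen. The X chromosome had few peaks. GC share, coding TSS and repeats, as matched here, did not account for all of this. Against autosomal bins of 100 kb alike in these, the X still had 0.199 ± 0.0344 of the covered bases (SD, n = 2, with 0.223 and 0.175 in the replicates). Matching raised the ratio from 0.0579. The classes were broad, the X held more repeats (46.6% against 33.5%), and how uniquely reads can be placed was not measured. Other features of its sequence were therefore not excluded. A signal lower by 1 factor along the X remains possible: at 0.2, 0.5 and 1 peak per Mb the fold on the X was 0.600 to 0.619 of that on the autosomes, a range of 0.0193. That factor may come from how the background was scaled or from the chromosome itself in the mixed pools of both sexes, and no test here parts these. Peaks on X genes such as Bcor (10.1 ± 4.31 kb) and Efnb1 (3.82 ± 1.95 kb) show that the chromosome was not left out of the calling.

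Genes of sclerotome and mesenchyme, which lies beside the tube, were high. CpG content of their promoters did not account for this, since the list stayed at percentile 100 among random lists matched on it. Mesenchymal cells in the dissected tissue could be a source. The collagen genes Col1a1 and Col1a2 and the receptor genes Pdgfra and Pdgfrb had a median of 4.00 kb, at percentile 73.5 of all coding genes. These 4 genes are members of the list itself, so their value is not separate from it. The highest fold near the list's genes was 0.908 of that near neural progenitor genes. Neither value decides the question. Use of these genes in the neural tube itself was not tested and stays open.

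The joint list had fewer peaks than either replicate. Merging of neighbouring peaks could not be the whole cause: the joint list covered 36.1 Mb, less than the 40.1 and 46.8 Mb of the replicates. Some merging beside a loss of peaks was not excluded. The joint list's median peak was 327 bp wide, against 278 bp in replicate 1 and 287 bp in replicate 2. Loss of peaks called in 1 replicate is a candidate explanation, since 30.8% of those peaks overlapped a peak of the joint list, against 96.9% of shared replicate 1 peaks. These shares restate the overlaps given in the results, so they describe the loss and are no separate test of it. The recorded values held no sign of a stricter cut-off for the joint list. Its lowest −log10 p, −log10 q and fold were reached by 124681 peaks of replicate 1 and 106277 of replicate 2, more than its 81261 peaks. The lowest −log10 p was 2.05 in the joint list, 2.01 in replicate 1 and 2.03 in replicate 2, so nearly all peaks had to pass. Values of a joint call need not be on the replicates' scale, so a difference in stringency was not excluded. No biological explanation was tested.

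Besides the rostral brain list, the ratio of covered kb in replicate 1 to replicate 2 was low for the cardiac (0.961; percentile 1.02), mesenchymal (0.984; percentile 1.57) and neuronal subtype lists (1.02; percentile 1.98), and high for the receptor list (1.25; percentile 100). Of the 1464 receptor genes 1293 had no peak, and neighbouring receptor genes share windows, which random lists do not copy. That percentile therefore decides little. This ratio was not among the measures planned beforehand.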
